A study of Mus musculus with 6 samples.

How the data were processed

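RNA was measured in 6 mouse libraries, 3 labelled wild type (WT) and 3 labelled as a conditional knockout of Srsf1 (Srsf1-cKO, with floxed Srsf1 and a dLck.Cre transgene). Each library came from naive CD4 T cells of a spleen, activated and restimulated in culture. The series' design text gives 3 mice for each genotype, and the sample labels number the libraries 1 to 3 within a genotype. Libraries were made with a stranded mRNA kit and read from one end over 75 bp, per the design text.

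Whole-number read counts per gene were deposited for all 6 libraries in one table, which names 24047 rows by gene symbol and holds no normalization. A second deposited table, also named as counts, held FPKM values (fragments scaled by transcript length and library depth) for 24043 rows. This unit was read from the values, which are not whole and which, set against the counts, give plausible transcript lengths. A deposited alignment report gave per-library metrics, such as the percent of reads mapped uniquely and the number of splices, and its header names STAR 2.4.2a. The submitters' processing notes name STAR, Cufflinks (no version) and the mm9 build. The annotation, the counting program and whether counting used the strand are not given in the sources used here, so reads of overlapping, antisense or near-identical genes may be shared. Among the genes named below this bears on Hspa1a and Hspa1b, on ribosomal protein genes, which have many pseudogene copies, and on Hnrnpa1. Dates stood in place of 27 gene names of the count table, as spreadsheet programs write them, and they were kept under those names (6 were called). No column of per-sample values was left unused.

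Counts were tested with edgeR 4.0.16 in R 4.3.3 by its quasi-likelihood test, two-sided, after filterByExpr and TMM scaling, with genotype as the only term and Benjamini-Hochberg adjustment. Genes with an adjusted p under 0.05 were called changed, and rose or fell is written only of those. The filter left 10454 genes. Log2 fold changes are Srsf1-cKO over WT, with their standard error (SE), and CPM values are gene counts scaled by TMM library size, given as mean ± SD over 3 libraries. FPKM values were tested with limma 3.58.1 on log2(FPKM + 1), with a trend, for the 9617 genes at 1 or more in at least 3 libraries. Folds on that scale understate the change of low genes. Single values were compared by exact two-sided permutation tests, whose smallest possible p with 3 against 3 libraries is 0.1. Library metrics were compared in the same way, with adjustment over 11 metrics.

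In all, 36 gene lists were fixed (pathways, markers of other cell types and signs of library quality), and the 30 with at least 5 tested members were tested with limma's camera on voom values at a preset correlation of 0.01, adjusted over the lists. The signs of library quality were the lists of heat shock, cytosolic ribosomal protein, replication-dependent histone, mitochondrially encoded and sex-linked genes. Camera with an estimated correlation and fry stand beside it. Hmgcs1, Noc2l and Ahsp from the lists had no row in the count table. The genes named are Srsf1, the 10 highest and 10 lowest log2 fold changes among called genes with a mean log2 CPM of at least 3 and no overlap between the groups, and, for each list, up to 4 members with the smallest adjusted p and its most abundant tested member. Genes outside this rule are marked as chosen after their values were seen, and some genes that the rule takes are not reported here. The lists, this rule, the tests and the alternatives were fixed before the data were examined, except where stated.

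The libraries hold between 7781283 and 10184268 gene counts, from 8924098 to 12007130 uniquely mapped reads. All pairs of replicates differed by more than sampling noise in a chi-square test of their counts. Counts simulated from the libraries' own means and spread, with 200 changed genes among 10348 tested, showed what this depth and spread allow with that number of changed genes. There edgeR called 5.97% of genes changed 1.5-fold, 67.2% of those changed 2-fold and 98.5% of those changed 4-fold, and 5% of its 120 calls were false. The real libraries gave far more calls and thus a looser adjusted cutoff, so these shares need not carry over to them. In simulated lists, camera found the list that had been moved and called 0 of 30 others, but genes were drawn independently there, so correlation between genes was not tried. limma on log2(FPKM + 1) recovered 59.7% of 2-fold changes among 9812 simulated genes.

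The alternatives were RLE, upper-quartile and library-size scaling, 2 other filters, DESeq2 1.42.0, limma-voom with and without sample weights, a replicate block, each library left out in turn, other thresholds, and the FPKM table. One more, leaving out the row of the 45S ribosomal RNA precursor (Rn45s), was chosen after the data were seen. Every library held Xist counts and none stood apart by Y-linked genes, so no sex term was fitted. Gene names, gene order and transcript lengths, GC content and junctions for further tests came from a GRCm38 reference (GENCODE M21) and a RefSeq gene table, of which 22634 of the 24045 symbols in the count table were found in GENCODE. That build is not the authors' mm9, so no coordinates are given. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.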

Results

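Gene expression was measured in CD4 T cells from the spleens of 7-week-old mice of a strain labelled B6.129. Naive cells were activated in culture for 72 h with antibodies to CD3 (0.5 µg/mL) and CD28 (1 µg/mL), which stand in for antigen and costimulation. They were then restimulated for 4 h with phorbol myristate acetate (PMA, 100 ng/mL) and ionomycin (1 µM), drugs that act downstream of the T cell receptor. The 3 WT libraries held 9650828, 7831945 and 7781283 gene counts, and the 3 libraries labelled Srsf1-cKO held 9123670, 8573465 and 10184268. On the first principal component of log2 CPM (56.1% of the variance) the WT libraries lay between -38.3 and -23.5 and the libraries labelled Srsf1-cKO between 26.0 and 35.9. The second component (23.0%) set WT replicate 2 (29.8) apart from WT replicate 3 (-35.2).

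Srsf1, which encodes a serine/arginine-rich (SR) splicing factor, is the targeted gene, and its mRNA was not lower in the libraries labelled Srsf1-cKO. Its counts were 4889, 3520 and 3679 in WT and 4839, 4911 and 5022 in the libraries labelled Srsf1-cKO, or 495 ± 42.1 and 514 ± 39.1 CPM (SD, n = 3 each). The log2 fold change was 0.06 (SE 0.12, 95% confidence interval -0.23 to 0.34, edgeR adjusted p = 0.78; exact permutation p = 0.7). A count over the whole gene can miss the loss of exons that hold a small share of its reads. Which exons the floxed alleles lose is not given in the sources used here. The lower end of the interval is a change of -14.5%, so it speaks against a larger net loss of Srsf1 reads, though not against a smaller one. Because the Srsf1 level does not bear out the labels, groups are called by their labels throughout. Every direction below is that of the libraries labelled Srsf1-cKO against WT. Without WT replicate 2, the Srsf1 log2 fold change was -0.0047.

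**Figure D1:**
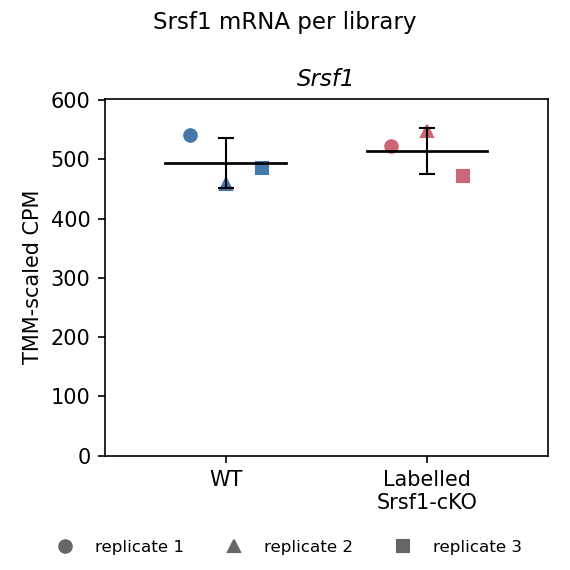
TMM-scaled CPM (y axis) of Srsf1 in each of the 6 libraries, with the mean (line) and SD (bar) of the 3 libraries of each labelled group (x axis). The values of both groups overlap, with means of 495 CPM in WT and 514 CPM in the libraries labelled Srsf1-cKO.

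The largest rises included cytokine genes, and the largest falls included heat shock genes. Among the 10 highest log2 fold changes were Il5 (5.04, SE 0.55), Il4 (4.29, SE 0.34) and Il13 (2.90, SE 0.41), which encode type 2 cytokines, Ifng (3.76, SE 0.58), which encodes interferon gamma, and Il24 (3.47, SE 0.63). The other 5 were Nov (4.06), P2ry1, an ADP receptor (3.24), Crtam, an adhesion receptor (3.06), Spp1, the gene of osteopontin (2.90), and Penk, the gene of proenkephalin (2.88). Among the 10 lowest were Hspa1a (-6.40, SE 1.15) and Hspa1b (-6.14, SE 1.00), near-identical copies that encode inducible HSP70 and whose reads may be shared. In WT replicate 3 they stood at 4.49 and 12.01 CPM, against 154 and 226 CPM in WT replicate 1. They also included Gm14085 (-3.54), Rab34 (-3.23), Nos2, the inducible nitric oxide synthase (-3.22), Fam213a (-2.49), the transcription factor gene Myb (-2.25), Id3, an inhibitor of E proteins (-2.20), and Ston1 (-2.17). The 19 named here passed with edgeR adjusted p between 0.00281 and 0.0223.

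Of 10454 genes tested, edgeR called 1923 (18.4%), with 930 higher and 993 lower in the libraries labelled Srsf1-cKO. The log2 fold change reached 1 in 400 of the higher genes and -1 in 359 of the lower ones. The groups' CPM values did not overlap for 4119 of the tested genes (39.4%, where chance gives 10%). With library-size scaling alone, 1268 were higher and 709 lower (64.1% higher against 48.4%), with the median log2 fold change of all genes at 0.11 instead of 0.01, so that changes on that scale are relative to 0.11. The count was most sensitive to WT replicate 1 and Srsf1-cKO replicate 2, at 195 without the former and 234 without the latter, and it was 1121 without Srsf1-cKO replicate 1. Each of the first pair, left out, leaves the replicates of its group that differed most in the chi-square test. Its value per degree of freedom was 39.7 for WT replicates 2 and 3 and 29.0 for Srsf1-cKO replicates 1 and 3. The lost calls thus need not mean that the changes themselves rest on the libraries left out. Of the 19 genes named above, 14, 18 and 19 passed without WT replicate 1, 2 and 3, and 19, 14 and 18 without Srsf1-cKO replicate 1, 2 and 3 (highest adjusted p of a lost call 0.0929). Single libraries moved some log2 fold changes, to 6.14 for Il5, 4.78 for Il24 and 3.57 for Il13 without WT replicate 2, to 4.78 for Ifng, -2.11 for Nos2 and -1.45 for Fam213a without WT replicate 3, and to 1.92 for Crtam without Srsf1-cKO replicate 3.

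Some genes of effector T cells rose, while the most abundant member of each of the 3 lists did not pass. Of 23 tested effector cytokine genes, 12 rose and 1 fell (13 and 1 adjusted over the list alone), with a median log2 fold change of 1.498. The list had camera adjusted p = 3.17e-06, and adjusted p = 0.444 with an estimated correlation. Il4 rose from 0.743 ± 0.394 to 14.8 ± 2.03 CPM, Il5 from 0.668 ± 0.678 to 22.1 ± 8.07, Il13 from 7.43 ± 5.10 to 55.4 ± 11.3, and Il10, the gene of a suppressive cytokine, from 1.198 ± 0.098 to 8.11 ± 3.33. The most abundant member, Il2, the T cell growth factor gene, did not pass, at 1223 ± 1246 CPM in WT and 1874 ± 602 in the libraries labelled Srsf1-cKO (adjusted p = 0.505). The member that fell, chosen after its value was seen, was Ltb, the gene of lymphotoxin beta, from 278 to 134 CPM. Of 20 chemokine and chemokine receptor genes, 9 rose and 0 fell (11 and 1 adjusted over the list alone; camera adjusted p = 0.00258, and adjusted p = 0.501 with an estimated correlation). Among them Cxcl2, Cxcl3 and Cxcl10 rose to at most 6.37 CPM, while Ccr4, the most abundant member, stood at 158 ± 35.8 and 123 ± 7.43 CPM (adjusted p = 0.173). Of 15 cytotoxic genes, 6 rose and 0 fell (10 and 0 adjusted over the list alone; camera adjusted p = 0.000497, and adjusted p = 0.444 with an estimated correlation). They included the NK receptor genes Klrk1 (0.173 to 6.81 CPM) and Klrd1 (0.854 to 7.92 CPM), the granzyme gene Gzmc (0.883 to 6.70 CPM), and Serpinb9, an inhibitor of granzyme B (176 ± 14.9 to 371 ± 90.8 CPM). Srgn, which packs granules, was the most abundant and did not pass (adjusted p = 0.0871).

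Of the 30 lists tested, 14 passed camera (11 higher and 3 lower), 8 passed fry, and 0 passed camera with an estimated correlation (1 at an unadjusted p under 0.05). Of the 8, 6 also passed camera, and the dendritic cell marker and apoptosis lists (fry adjusted p = 0.0315 and 0.038) did not. The chemokine list did not pass at a mean CPM of 5 or more (0.107) or by fry (0.0634), nor the cytotoxic list by fry (0.0554). In the cytokine, chemokine and cytotoxic lists 6, 1 and 1 genes rose without WT replicate 1. The numbers were 11, 1 and 3 without Srsf1-cKO replicate 2, and 10, 5 and 5 without Srsf1-cKO replicate 3. Of the 13 changed genes named in these lists, 6 passed without WT replicate 1 (adjusted p of the others up to 0.0841), among them Il4, Il5, Il13, Ifng and Il10, 9 passed without Srsf1-cKO replicate 2, and all 13 passed without each of the others. The log2 fold change of Klrk1, 5.26, was 4.62 without WT replicate 1 and 4.61 without Srsf1-cKO replicate 3, and no fold can be given without WT replicate 2, since WT replicates 1 and 3 held 0 Klrk1 counts, and that of Klrd1, 3.19, was 2.54 without Srsf1-cKO replicate 3. Il5 and Il13 stood at 6.14 and 3.57 without WT replicate 2, and Ifng at 4.78 without WT replicate 3. Lyz2, a myeloid marker, stood at 0.874 ± 1.09 CPM in WT and 7.31 ± 5.84 in the same libraries as these rises. Most tested markers of other cell types did not pass.

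**Figure D2:**
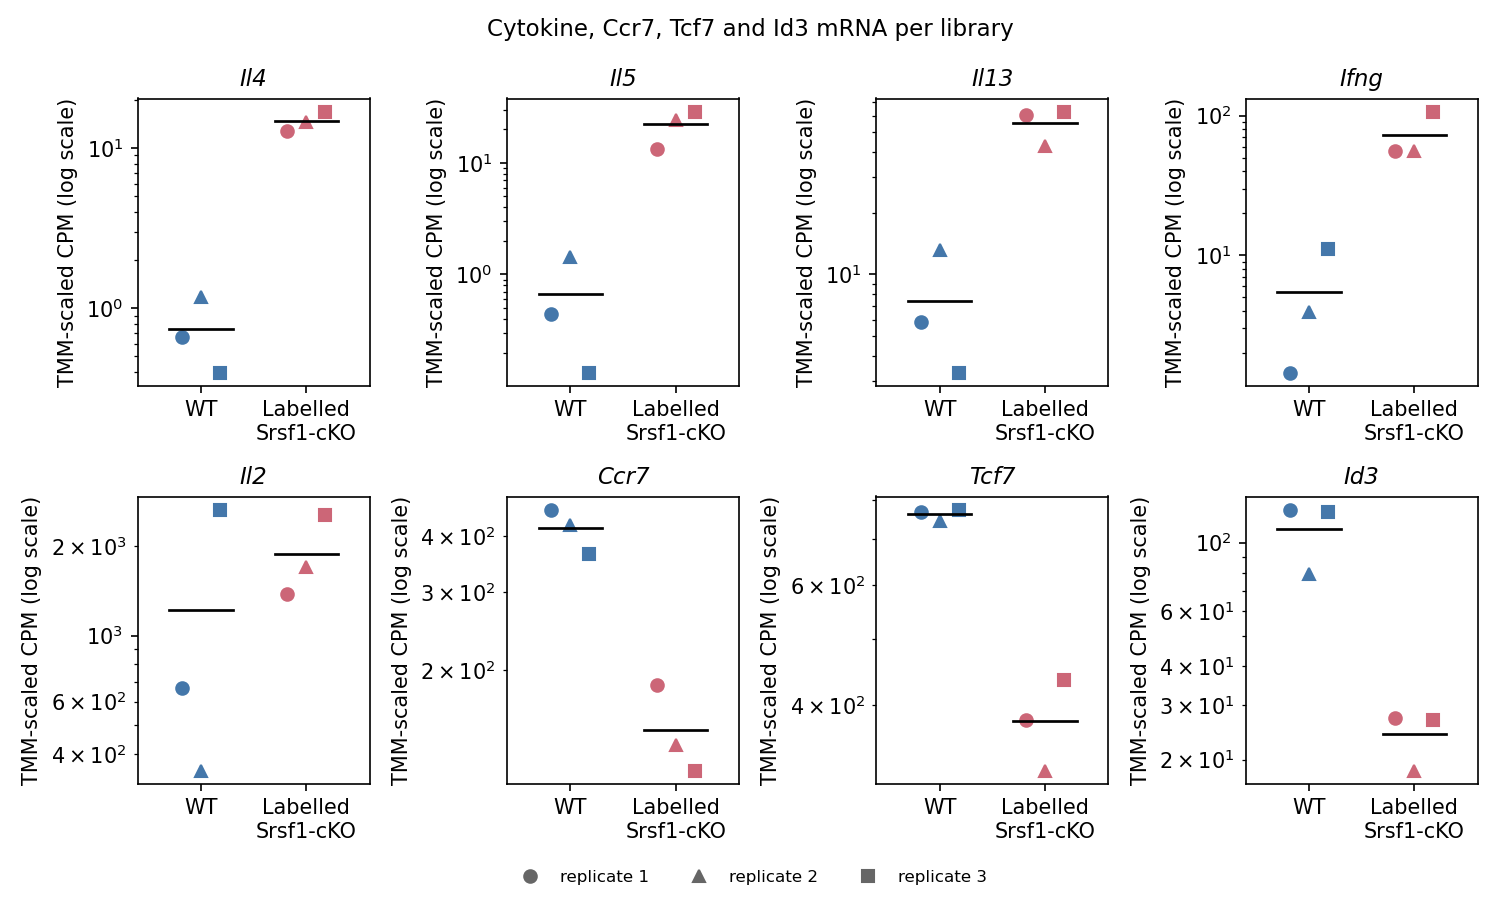
TMM-scaled CPM (y axes, log scale) of 8 genes in each library of both labelled groups (x axes), with the mean of the 3 libraries as a line. The values of Il4, Il5, Il13 and Ifng in the libraries labelled Srsf1-cKO lie above all WT values and those of Ccr7, Tcf7 and Id3 below them, while those of Il2 overlap.

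Some genes of naive and quiescent T cells fell, and some activation and receptor signalling genes changed in both directions. Of 22 naive and quiescence genes 6 fell and 0 rose (11 and 0 adjusted over the list alone; camera adjusted p = 0.00241, and adjusted p = 0.444 with an estimated correlation). Ccr7, a receptor for homing to lymph nodes, fell from 416 ± 47.1 to 147 ± 34.4 CPM, Tcf7, the gene of TCF1, from 762 ± 14.5 to 379 ± 57.6, the antiproliferative gene Btg1 from 1099.7 ± 189 to 526 ± 106 and Slfn1 from 149 ± 13.9 to 82.5 ± 15.6. The chromatin organizer gene Satb1 was the most abundant member and did not pass (log2 fold change 0.37, adjusted p = 0.547). Of 30 activation-induced genes 7 fell and 3 rose (7 and 6 adjusted over the list alone; camera adjusted p = 0.649), and the list's median (-0.10) and mean (0.04) log2 fold change differ in sign. Nr4a1, an early response gene of the T cell receptor, fell from 1129.9 ± 287 to 407 ± 114 CPM and the AP-1 gene Fosl2 from 190 ± 52.3 to 98.7 ± 19.9. Cd40lg, the gene of CD40 ligand, rose from 58.7 ± 22.3 to 263 ± 185 CPM and Tnfrsf8, the gene of CD30, from 1.38 ± 0.722 to 9.86 ± 1.78. The third rise, chosen after its value was seen, was Fos (24.7 to 46.3 CPM), and the most abundant member, Irf4, had adjusted p = 0.0643. With library-size scaling alone 5 activation-induced genes fell and 5 rose. In the same libraries some markers of other cell types were higher, with Lyz2 at 0.874 and 7.31 CPM, Cd79a at 0.525 and 2.30 and H2-Aa at 3.22 and 17.8, while most of those tested did not pass.

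Of 34 genes of the T cell receptor complex and its proximal signalling, 7 fell and 3 rose (8 and 3 adjusted over the list alone; camera adjusted p = 0.187). Rhoh (76.1 to 26.6 CPM), the diacylglycerol kinase gene Dgka (301 to 140 CPM) and the phosphatase gene Ptpn6 (196 to 104 CPM) were among those that fell, and Trat1, Cblb and Cd3g, chosen after their values were seen, rose with log2 fold changes of 1.04, 0.54 and 0.72. Ptprc, the gene of CD45 and the most abundant, did not pass (adjusted p = 0.124). Of 37 genes of the PI3K and mTOR pathway 3 fell and 0 rose, and 1 fell adjusted over the list alone (camera adjusted p = 0.121). Among these were Ddit4, which encodes an inhibitor of mTOR complex 1 (193 ± 59.8 to 76.5 ± 37.8 CPM), and the transcription factor gene Foxo3 (28.2 ± 3.49 to 18.6 ± 1.197 CPM), while Slc7a5, the most abundant, stood at 734 ± 64.0 and 701 ± 143 CPM (adjusted p = 0.804). In the naive, activation, receptor and PI3K lists 2, 0, 2 and 0 genes fell without WT replicate 1, and 7, 3, 5 and 4 without WT replicate 2. The numbers were 2, 1, 2 and 0 without Srsf1-cKO replicate 2, and 5, 2, 4 and 1 without Srsf1-cKO replicate 3. In addition, 5 PI3K genes fell without WT replicate 3 and 4 receptor genes without Srsf1-cKO replicate 1. In the activation and receptor lists 1 and 0 rose without WT replicate 1, and 6 and 2 without WT replicate 3. These were 3 and 1 without Srsf1-cKO replicate 1, 2 and 0 without Srsf1-cKO replicate 2, and 2 and 1 without Srsf1-cKO replicate 3. Of the 17 changed genes named in these 4 lists, 4, 13 and 16 passed without WT replicate 1, 2 and 3, and 13, 6 and 11 without Srsf1-cKO replicate 1, 2 and 3, with adjusted p of lost calls up to 0.184. Without Srsf1-cKO replicate 3 the log2 fold change of Cd40lg was 1.43 instead of 2.17.

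Some regulators of helper lineages changed, with 6 of 27 lower and 4 higher (7 and 5 adjusted over the list alone; camera adjusted p = 0.349). Id3 fell from 111 ± 27.5 to 24.1 ± 4.96 CPM, Runx3 from 92.8 ± 4.09 to 46.9 ± 5.40, and Eomes, a T-box factor of cytotoxic and memory cells, from 71.2 ± 17.2 to 20.8 ± 8.92. Foxp3, the factor that defines regulatory T cells, rose from 10.7 ± 1.96 to 31.3 ± 8.498 CPM. The other 3 rises, chosen after their values were seen, were Gata3, the factor of type 2 helper cells (38.5 to 85.4 CPM), Socs3 (13.5 to 26.7 CPM) and Ahr (13.9 to 24.1 CPM). Stat5a was the most abundant member and did not pass (962 ± 124 and 1052 ± 169 CPM, adjusted p = 0.597). Lyz2 and H2-Aa of other cell types were higher in the same libraries, at 7.31 and 17.8 CPM (0.874 and 3.22 in WT), while most such markers tested did not pass. Without WT replicate 1 the list had 2 lower and 0 higher, and without Srsf1-cKO replicate 2 it had 3 lower and 2 higher. Of the 7 changed genes named here, 2, 6 and 7 passed without WT replicate 1, 2 and 3, and 7, 5 and 6 without Srsf1-cKO replicate 1, 2 and 3, with adjusted p of lost calls up to 0.148.

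Some genes of the cell cycle rose, while the most abundant member of each list did not pass. Of 31 genes of G1/S and DNA replication 10 rose and 1 fell (14 and 1 adjusted over the list alone; camera adjusted p = 0.00261, and adjusted p = 0.601 with an estimated correlation). Rrm2, a subunit of ribonucleotide reductase, rose from 29.99 ± 3.79 to 85.9 ± 21.8 CPM, Tyms, thymidylate synthase, from 10.9 ± 1.28 to 39.5 ± 14.3, Cdk4 from 131 ± 8.71 to 213 ± 13.6, and the polymerase gene Pola1 from 36.6 ± 7.00 to 69.9 ± 13.6. The 1 that fell, chosen after its value was seen, was Rb1 (192 to 136 CPM), which encodes a brake on this transition, and the most abundant, the cyclin gene Ccnd2, stood at 2368 ± 614 and 2311 ± 241 CPM (adjusted p = 0.912). Of 30 G2/M genes 12 rose and 0 fell (20 and 0 adjusted over the list alone; camera adjusted p = 2.75e-08, and adjusted p = 0.560 with an estimated correlation). Ccna2, cyclin A, rose from 51.9 ± 23.0 to 156 ± 29.8 CPM, Cdk1 from 50.4 ± 7.54 to 113 ± 24.5, and the mitotic kinase genes Aurka and Plk1 with log2 fold changes of 0.78 and 0.81. Top2a was the most abundant and did not pass (584 ± 223 and 755 ± 64.5 CPM, adjusted p = 0.302). Replication-dependent histone genes were listed as a sign of library quality, and 6 of the 68 in the count table were tested. Of these 6 histone genes 3 rose and 0 fell (5 and 0 adjusted over the list alone), all under 5 CPM (Hist1h1d, Hist1h2bc and Hist1h4i), and Hist1h1c, the most abundant, had adjusted p = 0.0935. Their list had camera adjusted p = 0.0393, and adjusted p = 0.444 with an estimated correlation. The number of G2/M genes that rose was 0 without WT replicate 1, 1 without Srsf1-cKO replicate 2 and 24 without WT replicate 2, and that of G1/S genes was 2 without either of the first pair. Of the histone genes 0 rose without WT replicate 1 or Srsf1-cKO replicate 2 or 3. The histone list did not pass without WT replicate 3 (0.121) or Srsf1-cKO replicate 3 (0.0712), under library-size scaling (0.0770), with sample weights (0.138) or with a replicate block (0.0594), and neither cell cycle list passed by fry (0.119 and 0.0961). The markers Cd79a and Lyz2 of other cell types were higher in the same libraries as these rises, at 2.30 and 7.31 CPM (0.525 and 0.874 in WT). Most such markers tested did not pass. Of the 12 changed genes named here, 2, 9 and 10 passed without WT replicate 1, 2 and 3, and 8, 3 and 8 without Srsf1-cKO replicate 1, 2 and 3, with adjusted p of lost calls up to 0.160.

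Most genes of cytosolic ribosomal proteins fell. Of 77 tested, 69 fell and 1 rose (72 and 1 adjusted over the list alone), with a median log2 fold change of -0.71. The camera adjusted p was 1.88e-29, and adjusted p = 0.465 with an estimated correlation. They took 9.33% ± 1.01 of counts in WT and 6.10% ± 0.354 in the libraries labelled Srsf1-cKO (SD, n = 3 each; exact permutation p = 0.1, the smallest possible, 0.22 adjusted over 11 metrics; lower in 3 of 3 libraries than in any WT library). Rpl22l1 fell from 444 ± 39.1 to 180 ± 23.8 CPM, Rpl36 from 380 ± 88.6 to 145 ± 26.0, Rpl10a from 495 ± 64.2 to 258 ± 18.5, Rpl17 from 2705 ± 171 to 1503 ± 147, and the most abundant, Rpl4, from 5577 ± 536 to 3412 ± 250. The member that rose, chosen after its value was seen, was Rps27l (87.9 to 135 CPM). Some markers of other cell types were higher in these libraries (Lyz2 at 7.31 CPM, Cd79a at 2.30 and H2-Aa at 17.8), while most of those tested did not pass. The number that fell was 10 without WT replicate 1 and 7 without Srsf1-cKO replicate 2, and lay between 57 and 71 without each of the others. The median of the list was -0.65 and -0.66 without those libraries, -0.61 with library-size scaling and -0.60 in the FPKM table.

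A few energy metabolism genes changed, in a direction that differed by list. Of 23 glycolysis genes 3 fell and 0 rose (1 and 0 adjusted over the list alone; camera adjusted p = 0.0308, and adjusted p = 0.626 with an estimated correlation). They were Gpi1 (1090.2 ± 362 to 514 ± 93.3 CPM), Aldoa (2235 ± 1055 to 973 ± 129 CPM) and Pfkm (33.6 ± 8.75 to 17.2 ± 5.96 CPM), enzymes of the upper part of the pathway, while Pkm, the most abundant, did not pass (adjusted p = 0.130). Of 32 oxidative phosphorylation genes 5 rose and 0 fell, also adjusted over the list alone (camera adjusted p = 0.0211, and adjusted p = 0.688 with an estimated correlation). They were the respiratory chain and ATP synthase genes Atp5j, Sdhb, Ndufb8, Ndufa4 and, chosen after its value was seen, Uqcrc1, with log2 fold changes from 0.47 to 0.91. Atp5b, the most abundant, stood at 0.11 (adjusted p = 0.552). With library-size scaling alone 10 oxidative phosphorylation genes rose and 0 fell, and 2 glycolysis genes fell and 1 rose. Without WT replicate 1, 2 and 3, 0, 1 and 11 glycolysis genes fell and 0, 4 and 3 oxidative phosphorylation genes rose. Without Srsf1-cKO replicate 1, 2 and 3 the numbers were 2, 0 and 2, and 4, 0 and 2. Lyz2 and H2-Aa were higher in the same libraries, at 7.31 and 17.8 CPM (0.874 and 3.22 in WT), while most tested markers of other cell types did not pass. The glycolysis list did not pass without WT replicate 1 (0.0948), WT replicate 2 (0.222) or Srsf1-cKO replicate 3 (0.0673), by fry (0.436) or at a mean CPM of 5 or more (0.0668), and the oxidative phosphorylation list did not pass without WT replicate 3 (0.115) or Srsf1-cKO replicate 3 (0.190), by fry (0.211) or with sample weights (0.177). Of the 14 changed ribosomal and metabolic genes named in these lists, 4, 9 and 11 passed without WT replicate 1, 2 and 3, and 11, 4 and 8 without Srsf1-cKO replicate 1, 2 and 3, with adjusted p of lost calls up to 0.159.

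**Figure D3:**
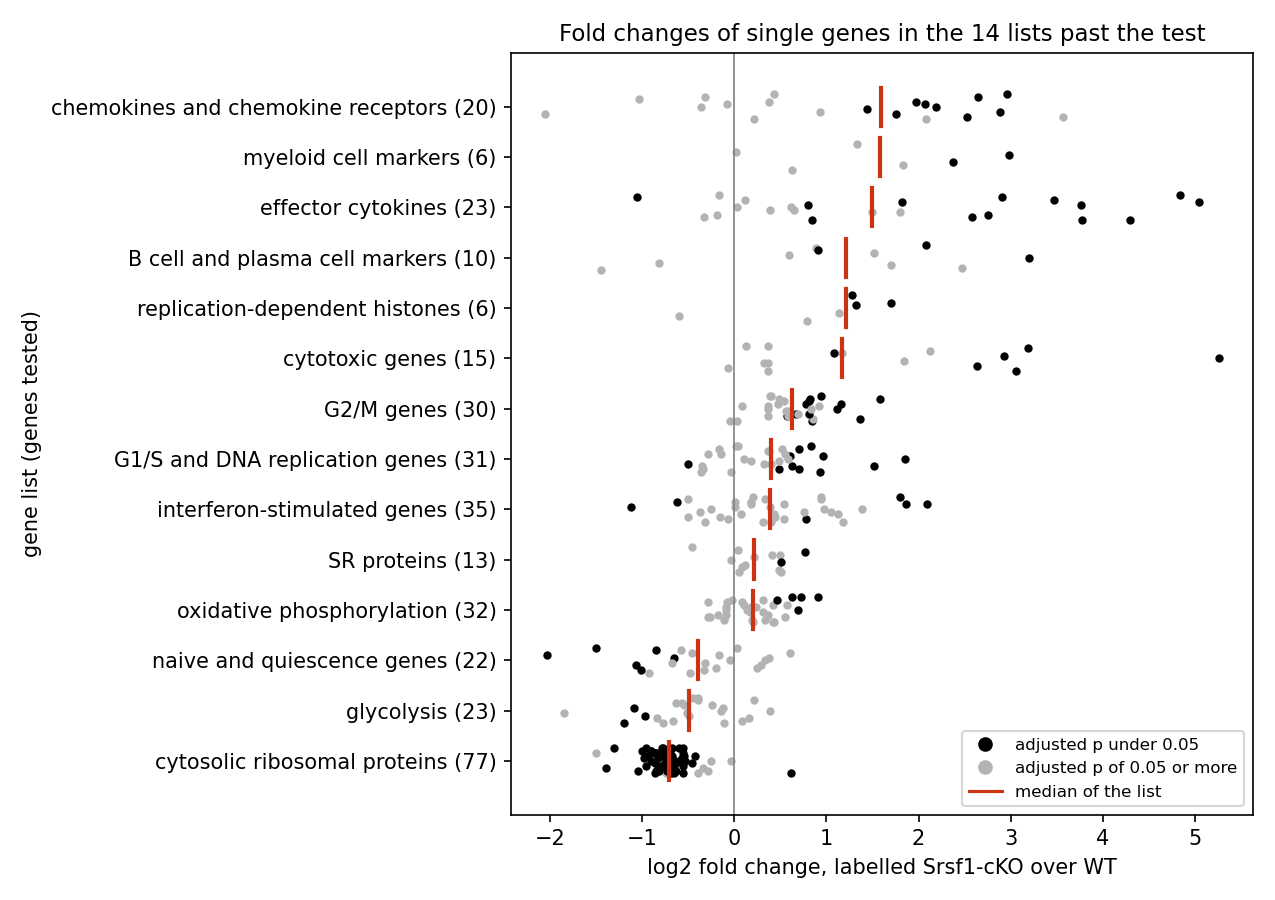
Log2 fold change (x axis, libraries labelled Srsf1-cKO over WT) of each tested gene in the 14 lists that passed camera (y axis, number of genes tested in brackets), black for an adjusted p under 0.05 and grey otherwise, with the median of each list as a red line. The medians run from -0.71 for ribosomal protein genes to 1.60 for chemokines and their receptors.

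Other genes of RNA processing changed in small number. Of 13 SR protein genes, Srsf7 (263 ± 17.7 to 447 ± 53.03 CPM) and Srsf9 (64.1 ± 4.32 to 91.5 ± 8.08 CPM) rose and 0 fell, also adjusted over the list alone (camera adjusted p = 0.0393, and adjusted p = 0.592 with an estimated correlation). Of 40 hnRNP and spliceosome genes 4 rose and 4 fell, also adjusted over the list alone (camera adjusted p = 0.632). Hnrnpd rose from 272 ± 21.7 to 462 ± 3.50 CPM, Srpk1, an SR protein kinase, fell from 246 ± 15.1 to 150 ± 21.1, and Hnrnpa1 and the kinase gene Clk4 fell with log2 fold changes of -0.81 and -0.68. The remaining 4, chosen after their values were seen, were Hnrnpa3, Hnrnpll and Snrpd1 (log2 fold changes of 0.73, 0.65 and 0.43) and Clk1 (-0.77). Hnrnpu, the most abundant, did not pass (1481 ± 85.9 and 1614 ± 77.2 CPM, adjusted p = 0.468). The SR protein list did not pass without WT replicate 2 (0.115), Srsf1-cKO replicate 1 (0.0858) or Srsf1-cKO replicate 2 (0.0818), or by fry (0.101). Without WT replicate 1, 2 and 3, 0, 1 and 2 SR protein genes rose, and 1, 0 and 4 without Srsf1-cKO replicate 1, 2 and 3. Of the hnRNP and spliceosome genes 0 changed without WT replicate 1, and 1 rose and 0 fell without Srsf1-cKO replicate 2, while 2 rose without WT replicate 2 or Srsf1-cKO replicate 1. With library-size scaling alone 8 of them rose and 4 fell. Lyz2 and H2-Aa stood higher in these libraries too, at 7.31 and 17.8 CPM (0.874 and 3.22 in WT), while most tested markers of other cell types did not pass.

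Of 35 interferon-stimulated genes 4 rose and 2 fell, also adjusted over the list alone (camera adjusted p = 0.0393, and adjusted p = 0.444 with an estimated correlation). Ifit1 (4.73 ± 1.23 to 19.97 ± 11.6 CPM), Ifit3 (2.07 ± 0.656 to 7.26 ± 1.98 CPM), Cmpk2 (0.477 to 1.80 CPM) and Ifi27l2a (43.5 to 74.3 CPM) rose, while the GTPase gene Gbp2, the most abundant member, fell from 819 ± 206 to 376 ± 84.5 CPM and the peptide transporter gene Tap1 from 354 to 231 CPM. Ifi27l2a and Tap1 were chosen after their values were seen. The list did not pass without WT replicate 1 (0.101) or Srsf1-cKO replicate 3 (0.0518), under library-size scaling (0.0751), at a mean CPM of 5 or more (0.370) or in the FPKM table (0.187). Lyz2 and Cd79a were higher in the libraries labelled Srsf1-cKO, at 7.31 and 2.30 CPM (0.874 and 0.525 in WT), while most tested markers of other cell types did not pass. Of 15 heat shock genes 5 fell and 0 rose, also adjusted over the list alone (camera adjusted p = 0.109). Besides Hspa1a and Hspa1b these were Hspa8, the constitutive HSC70 (2395 ± 199 to 1497 ± 139 CPM), the co-chaperone gene Bag3 (21.2 ± 3.88 to 11.5 ± 1.19 CPM) and, chosen after its value was seen, Dnajb1 (81.6 to 50.1 CPM). Hsp90ab1, the most abundant, did not pass (4338 ± 331 and 3957 ± 31.9 CPM, adjusted p = 0.443). Of the 21 changed genes named in these RNA processing, interferon and heat shock lists, 1, 14 and 16 passed without WT replicate 1, 2 and 3, and 14, 4 and 12 without Srsf1-cKO replicate 1, 2 and 3, with adjusted p of lost calls up to 0.164. Of the interferon-stimulated genes 0, 8 and 5 rose and 0, 1 and 2 fell without WT replicate 1, 2 and 3. Among them 2, 2 and 3 rose and 1, 0 and 1 fell without Srsf1-cKO replicate 1, 2 and 3. Without WT replicate 1 or Srsf1-cKO replicate 2, 1 heat shock gene fell. Without Srsf1-cKO replicate 3 the log2 fold change of Ifit1 was 1.497 instead of 2.09.

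Some markers of other cell types rose, mostly at low CPM, while most of those tested did not pass and Eomes fell. Of 10 tested B cell and plasma cell markers 3 rose and 0 fell (5 and 0 adjusted over the list alone; camera adjusted p = 0.0454, and adjusted p = 0.557 with an estimated correlation). They were Pou2af1, a coactivator that T cells also express (40.7 ± 4.89 to 76.5 ± 10.7 CPM), Cd79a (0.525 ± 0.346 to 2.30 ± 0.628 CPM) and Fcer2a, the gene of CD23 (1.12 ± 0.967 to 10.6 ± 7.82 CPM). Of 6 tested myeloid markers 2 rose and 0 fell (3 and 0 adjusted over the list alone; camera adjusted p = 0.0308, and adjusted p = 0.444 with an estimated correlation). They were Cybb, a subunit of the phagocyte oxidase (2.28 ± 1.98 to 11.9 ± 4.02 CPM), and the lysozyme gene Lyz2 (0.874 ± 1.09 to 7.31 ± 5.84 CPM), while the most abundant, Cebpb, stood at 21.3 ± 0.896 and 21.6 ± 5.54 CPM (adjusted p = 0.958). Of 7 dendritic cell markers 2 rose and 0 fell (3 and 0 adjusted over the list alone; camera adjusted p = 0.133, fry adjusted p = 0.0315), the MHC class II gene H2-Aa (3.22 ± 2.405 to 17.8 ± 6.77 CPM) and Cd74 (45.1 ± 8.87 to 81.7 ± 5.999 CPM). Among 3 tested NK and innate lymphoid markers, too few for the list test, Il1rl1 and Kit rose and Eomes fell, also adjusted over the list alone.

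The only CD8 marker tested, Cd8b1, stood at 30.4 ± 10.2 and 19.95 ± 3.14 CPM (adjusted p = 0.115), and counts as lower adjusted over the list alone. The only erythroid marker tested, Car2, had adjusted p = 0.392, and the only sex-linked gene tested, Xist, 0.151, neither passing adjusted over the list alone, and 0 stromal markers and 0 mitochondrially encoded genes were tested. Of the 10 changed markers of other cell types named here, 1, 8 and 10 passed without WT replicate 1, 2 and 3, and 7, 1 and 7 without Srsf1-cKO replicate 1, 2 and 3, with adjusted p of lost calls up to 0.146. In the B cell, myeloid and dendritic cell lists 1, 0 and 0 rose without WT replicate 1, 4, 2 and 4 without WT replicate 2, and 3 in each without WT replicate 3. In the same lists 1, 2 and 2 rose without Srsf1-cKO replicate 1. The numbers were 0 in each without Srsf1-cKO replicate 2, and 3, 1 and 3 without Srsf1-cKO replicate 3. The log2 fold change of Lyz2, 2.98, was 4.72 without WT replicate 1 and 2.10 without Srsf1-cKO replicate 3, and those of Cybb and H2-Aa, 2.38 and 2.47, were 3.23 and 3.24 without WT replicate 2. The B cell list did not pass without WT replicate 3 (0.0645) or Srsf1-cKO replicate 1 (0.0512), under upper-quartile (0.0548) or library-size scaling (0.118), by fry (0.0957) or in the FPKM table (0.184), and the myeloid list not under library-size scaling (0.0510).

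The deposited FPKM values of the same libraries gave a second quantification, though not a second experiment. In limma's test 1801 of 9617 genes passed, 1186 higher and 615 lower (65.9% higher), with a median log2 fold change of 0.10 over all genes. Of 1761 genes called from counts and tested in both tables, 1426 were called from FPKM in the same direction and 0 in the opposite one. Across the 9384 genes tested in both, which are not independent replicates, the log2 fold changes had a Pearson correlation of 0.953. Srsf1 stood at 65.7 ± 3.24 and 73.6 ± 6.27 FPKM (adjusted p = 0.351). The count of calls was 91 without WT replicate 1, 64 without Srsf1-cKO replicate 2, 838 without Srsf1-cKO replicate 1 and 1086 without Srsf1-cKO replicate 3.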

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

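The alignment report held signals that none of the comparisons above used, and the percents of AT/AC splices and of mismatches lay in every library labelled Srsf1-cKO above every WT library. AT/AC splices, an intron class with rare end sequences, made up 0.0777% ± 0.0033 of splices in WT and 0.0937% ± 0.00282 in the libraries labelled Srsf1-cKO (SD, n = 3 each; exact permutation p = 0.1, 0.22 adjusted over 11 metrics). GC/AG splices went the other way and were lower in every library labelled Srsf1-cKO than in every WT library, at 1.28% ± 0.0224 in WT and 1.11% ± 0.033 (exact permutation p = 0.1, 0.22 adjusted). The mismatch rate per base was 1.17% ± 0.0173 and 1.23% ± 0.0252 (exact permutation p = 0.1, 0.22 adjusted). No exact permutation test with 3 against 3 libraries can go below p = 0.1. Groups of 3 are too small for a test of single outlying samples, and no such test was run.

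Splices per 100 uniquely mapped reads were also lower in every library labelled Srsf1-cKO than in every WT library, at 27.0 ± 0.134 against 29.3 ± 1.29 (exact permutation p = 0.1, 0.22 adjusted over 11 metrics), a difference of 7.87%. The mix of expressed genes may account for part of it. The junctions per read expected from each library's gene counts and annotated transcripts fell by 2.07%, which is 26.3% of the observed difference, and by 0.0625% when ribosomal protein genes were left out. Observed over expected splices still averaged 0.911 ± 0.00412 against 0.968 ± 0.0307 (exact permutation p = 0.1). That part lies between the bounds set in advance, so the mix of genes and other sources, such as read trimming, unspliced RNA or the genotype, cannot be told apart here.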

How the results depend on the processing

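Every alternative was set before the data were examined except the one without Rn45s, which gave 1928 changed genes and 14 lists. The count of changed genes, 1923, lay between 1659 and 2289 under the other scalings, filters, DESeq2, unweighted limma-voom, a replicate block and the FPKM table. It was 4355 with sample weights, 759 with an absolute log2 fold change of 1 or more, 945 by glmTreat against 1.2-fold, 279 at an adjusted p of 0.01 and 2972 at 0.1, where the alternative itself sets a wider or narrower call except for the weights, whose effect had a cause that was not tested. It ran from 195 to 1989 with single libraries left out. Srsf1 ran from -0.0047 to 0.12 with single libraries left out, changing sign without WT replicate 2 (the cause was not tested), and reached 0.16 with library-size scaling and in the FPKM table, never called. Of 30 lists 14 passed, and 18 of 34 with no filter on low counts, 15 without shared genes, 10 by library size, 11 of 29 in the FPKM table, 10 to 14 with single libraries left out, 8 of 27 at a mean CPM of 5 or more, 8 by fry, and 0 with an estimated correlation (1 at an unadjusted p under 0.05). The causes were not tested, though the stricter filter leaves fewer genes. From FPKM, 1146 genes passed with no filter on low values, where more genes are tested, and 64 to 1852 with single libraries left out. Among 2965 values of the other 166 named genes, 2543 kept direction and call, 380 lost and 29 gained it, and 13 changed sign, all in genes never called there: Slc7a5 (0.0351 by library size, 0.0181 in the FPKM table, -0.20 to 0.087 with single libraries left out), Ccnd2 (0.0669, 0.0896, -0.18 to 0.18), Cebpb (-0.0247 by limma-voom, -0.0077 with a replicate block, -0.15 to 0.21) and Car2 (-0.64 to 0.0037); the cause was not tested. Whether the replicate number pairs the samples stays open, since so few libraries per group cannot settle it. Same-numbered libraries' deviations correlated at 0.22, 0.01 and 0.27. Replicates 1 and 3 of each group correlated best with their own number in the other group, and replicate 2 of neither group did. A replicate block gave 2270 genes from counts, 2039 from FPKM and 14 lists. A sex term was not run, since no library stood apart by sex-linked genes, and DESeq2 was not run for lists. Depth and spread limit small changes: 5.97% of simulated 1.5-fold changes were called.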

Other observations

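The tests of explanations for the Srsf1 mRNA level and the test of the wider class of translation mRNAs were chosen only after the results were seen. Further gene groups changed in parts, in the libraries labelled Srsf1-cKO against WT, and none of their lists passed camera. Of 26 cytokine receptor genes, Il1rl1, the receptor of interleukin 33, rose (0.329 to 1.96 CPM) and Il4ra fell (189 ± 27.5 to 127 ± 17.3 CPM), and 1 rose and 0 fell adjusted over the list alone (camera adjusted p = 0.498). Il2ra was the most abundant (3801 ± 111 and 4905 ± 474 CPM, adjusted p = 0.0641). Of 15 inhibitory receptor genes, Btla rose (190 ± 23.4 to 324 ± 27.9 CPM) and Nt5e, Lag3 and Cd274 fell, the last, which encodes PD-L1, from 516 ± 49.5 to 340 ± 62.9 CPM, and 3 rose and 3 fell adjusted over the list alone (camera adjusted p = 0.939), with Cd5, the most abundant, at adjusted p = 0.324. Of 15 regulatory T cell genes, Foxp3, Il10 and Gpr83 rose and Ikzf4 fell, and 6 rose and 1 fell adjusted over the list alone (camera adjusted p = 0.109). Of 27 adhesion and trafficking genes 3 rose and 6 fell, also adjusted over the list alone (camera adjusted p = 0.780). Itgav, the integrin alpha V gene, rose from 285 ± 5.06 to 581 ± 101 CPM, Anxa1 and, chosen after its value was seen, Lgals1 rose as well, and Icam1 and S1pr4 fell with log2 fold changes of -0.93 and -0.91, while Vim, the most abundant, did not pass. Without WT replicate 1 or Srsf1-cKO replicate 2, 0 adhesion genes fell and 2 rose, and 2 fell without Srsf1-cKO replicate 1. In the cytokine receptor, inhibitory receptor and regulatory T cell lists 0, 0 and 1 rose and 0, 1 and 0 fell without WT replicate 1. The numbers were 2, 1 and 3 and 2, 2 and 0 without WT replicate 2, and 2, 4 and 2 and 4, 3 and 3 without WT replicate 3. They were 1, 3 and 2 and 0, 1 and 0 without Srsf1-cKO replicate 1, and 0, 0 and 2 and 0, 0 and 0 without Srsf1-cKO replicate 2. Without Srsf1-cKO replicate 3, 1, 1 and 2 rose and 0, 3 and 0 fell.

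Of 27 apoptosis regulators 4 fell and 0 rose, and 3 fell adjusted over the list alone (camera adjusted p = 0.297, fry adjusted p = 0.038). They were Bmf, a proapoptotic BH3-only gene (9.82 ± 4.85 to 1.195 ± 0.335 CPM), Tnfrsf1a, Apaf1 and Ripk1, and the most abundant, Cflar, did not pass. Of 27 p53 target genes Perp rose (4.35 ± 0.965 to 23.3 ± 5.03 CPM), and Bbc3, the gene of PUMA (24.9 ± 7.71 to 6.89 ± 1.04 CPM), and Ercc5 fell, also adjusted over the list alone (camera adjusted p = 0.713), the list's median (-0.09) and mean (0.06) differing in sign and Trp53inp1, the most abundant, not passing. Of 26 cholesterol and fatty acid synthesis genes Mvd (46.0 ± 4.68 to 19.8 ± 1.46 CPM) and Lss fell and 0 rose, and 1 fell adjusted over the list alone (camera adjusted p = 0.0747). Of 30 genes of the unfolded protein and amino acid stress response 2 rose and 4 fell, and 3 rose and 5 fell adjusted over the list alone (camera adjusted p = 0.649). The rises were Pdia4 and, chosen after its value was seen, Ern1, and Atf5 (53.6 ± 8.10 to 16.6 ± 7.78 CPM), Atf3 and Ppp1r15a and, chosen after its value was seen, Vegfa fell, while Hspa5, the most abundant, did not pass and the list's median (0.13) and mean (-0.01) differ in sign. Of 29 ribosome biogenesis genes Nop56 rose and Gnl3 and Npm1 fell, and 1 rose and 1 fell adjusted over the list alone (camera adjusted p = 0.713), with Ncl, the most abundant, at adjusted p = 0.385. Of the 33 changed genes named in these lists, 8, 24 and 28 passed without WT replicate 1, 2 and 3, and 18, 8 and 22 without Srsf1-cKO replicate 1, 2 and 3, with adjusted p of lost calls up to 0.164. In the apoptosis, p53, cholesterol and stress response lists 1, 1, 1 and 0 genes fell without WT replicate 1, 2, 4, 6 and 4 without WT replicate 2, and 5, 3, 1 and 4 without WT replicate 3. The numbers were 1, 3, 1 and 3 without Srsf1-cKO replicate 1, 1, 1, 1 and 0 without Srsf1-cKO replicate 2, and 1, 2, 1 and 3 without Srsf1-cKO replicate 3. In the apoptosis and cholesterol lists 2 and 2 rose without WT replicate 3. In the stress response list 0, 1 and 1 rose without WT replicate 1, 2 and 3, and 0, 0 and 4 without Srsf1-cKO replicate 1, 2 and 3. With library-size scaling alone 6 genes of that list rose and 4 fell. Of the ribosome biogenesis genes 0, 0 and 1 rose and 0, 2 and 2 fell without WT replicate 1, 2 and 3, and 0, 0 and 1 rose and 0 fell without Srsf1-cKO replicate 1, 2 and 3. Lyz2 and H2-Aa, markers of other cell types, were higher in the same libraries, at 7.31 and 17.8 CPM (0.874 and 3.22 in WT), while most such markers did not pass.

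The 6 samples can be divided 3 against 3 in 10 ways, too few for a share under 0.05. The real grouping gave 1923 changed genes in edgeR, and the highest other grouping gave 0 (736 at an unadjusted p under 0.05, against 3644), so 1 of 10 groupings reached the real count. Every other grouping mixes both labelled groups, so their difference widens the spread within a group and holds gene counts down. Such low counts do not show what libraries without a difference would give. From FPKM the real grouping gave 1801 and the highest other 2, so again 1 of 10 reached it. For the gene lists 2 of 10 groupings reached 14, because WT replicates 1 and 3 with Srsf1-cKO replicate 1 against the rest also gave 14. Every other mixed grouping called lists too, between 4 and 13, with 0 genes called by edgeR in each, so a count of lists from camera at the preset correlation does not by itself set the labelled groups apart.

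The level of Srsf1 mRNA in the libraries labelled Srsf1-cKO is open to several explanations. If the first principal component follows the genotype, a swap of some libraries between the groups would leave a library of each group on the other's side. The groups were 49.5 apart there with none out of place. The Srsf1 mRNA level does not tie that component to the genotype, so such a swap stays open if the component follows another difference. An exchange of all 6 labels would leave the same gap, so whether one took place stays open. It would only turn the sign of the Srsf1 log2 fold change of 0.06 (SE 0.12). Srsf1 stood at 540, 458 and 486 CPM in WT and at 523, 548 and 471 CPM in the libraries labelled Srsf1-cKO. These values overlap, which argues against such an exchange as the reason why Srsf1 mRNA was not lower. Reads from exons outside a deleted part may keep the gene count up. The log2 ratio of FPKM to counts of Srsf1 moved by 0.0021 between the groups, which does not settle it, since a change in the mix of transcripts need not move that ratio, and incomplete deletion likewise cannot be told apart from it without reads per exon.

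The fall of ribosomal protein mRNAs stayed under every scaling tried, and the median log2 fold change closest to 0 over the scalings and the FPKM table was -0.60. Scaling shifts all genes of a library alike, and the median of all genes was 0.01 with TMM and 0.11 by library size. This comparison could thus hardly have come out otherwise. It shows a fall relative to other genes and cannot see a change in total mRNA per cell. Removing the trend on transcript length, GC content and abundance fitted on the other genes (all 77 members had values) left a median of -0.72 (SD 0.272 over genes). Such a bias thus does not account for the fall. In 44 other genes as short and as abundant the median was 0.08. The fall may belong to the wider class of mRNAs with a 5' terminal oligopyrimidine tract, whose translation mTOR controls. In 23 such genes that encode no ribosomal protein of the tested list, 3 of which other lists hold, 17 fell and 0 rose, among them Eef2, Eef1a1, Gas5, Tpt1 and Pabpc1 (chosen after their values were seen; 2, 5 and 5 of these 5 passed without WT replicate 1, 2 and 3, and 5, 2 and 4 without Srsf1-cKO replicate 1, 2 and 3), while Vim did not pass, and their median was -0.63 (SD 0.318), with 4 lower without WT replicate 1 and 3 without Srsf1-cKO replicate 2 (medians -0.56 and -0.59), a hypothesis formed and tested on the same libraries that leaves cell state and cell mixture open.

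Among the 200 tested genes nearest to Srsf1 in gene order, 46 (23.0%) were called, against 1779 of 9708 elsewhere (18.3%), an odds ratio of 1.33 (95% confidence interval 0.93 to 1.87, Fisher's exact p = 0.0970), so flanking DNA of the targeting strain was neither shown nor excluded. The log2 ratio of FPKM to counts changed for 5 of 7441 genes (Cenpl, Fam120b, Prr3, Polr1d and Dido1, chosen after their values were seen), and 1 of 10 groupings reached 5, with 0 as the highest other (limma, and no other tool was run). The other groupings mix both labelled groups, which can hold such counts down.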
